A study of Rattus norvegicus with 4 samples.

How the data were processed

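Total RNA from NR8383 cells was measured on one-colour Agilent rat arrays. The labels give 4 samples, all exposed for 4 h to 1.2 cm²/cm² of NRCWE049 nanotubes after 48 h in culture; RNA integrity was above 7.5, and 100 ng of RNA were labelled with Cy3, per the labels' protocols. The samples form 1 group of 4 biological replicates, per the series' design text. The unexposed controls of that design were not analysed here, so no comparison between groups was made. The 4 arrays lay on 1 slide scanned in 1 run, per the file headers, so slide and scan could not be tested as batches, and the position on the slide cannot be told apart from the replicate.

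The deposited intensity of each spot is Agilent's background-corrected processed signal, made with Feature Extraction 11.0.1.1, per the submitters' processing notes and the file headers. Any normalization between arrays by the authors is not given in the sources used here. Each array held 62976 spots, of which 4259 were control spots. Control spots and spots flagged as nonuniform or population outliers were left out, replicate spots of a probe were averaged on the log2 scale, and no spot was saturated. A probe was detected where Agilent's flag for signal well above background held for most of its spots, on 4 of 4 arrays. Because 39.3% of the probes were detected on all arrays, the level was the log2 processed signal minus the 75th percentile over these probes; that percentile was at a signal of 1970, 1980, 2493 and 2402.5 in replicates 1 to 4. The median CV of replicate spots was 14.1%, 11.2%, 11.1% and 11.9%.

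Accessions in the files were matched without versions to a RefSeq gene table of the GRCr8 assembly, which differs from the build in the file headers, so no coordinates are given. Of 45598 probes, 21109 were named, giving 16581 genes; 24489 stayed unnamed, of which 28.8% were detected against 51.4% of the named probes. Of 436 members of the 28 lists, 414 were measured. A gene counted as detected if at least 1 probe was, and its level came from the brightest probe, detected ones first. Of 3658 genes with several probes, 803 had probes that disagreed on detection. A gene with 1 probe that was not detected may therefore still be expressed.

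List detection was compared with all other named genes by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over 28 lists. An infinite odds ratio was replaced by one with 0.5 added to each count. Variation between replicates was tested with limma 3.58.1 in R 4.3.3, from an intercept fit, by an F test of each gene's residual variance against that expected at its intensity, adjusted at 0.05 over 8713 genes. For lists with at least 5 detected members, the range over arrays of the list's mean deviation was set against 10000 random lists matched in 20 bins of signal. Files were read with the R package data.table (version 1.17.8) and figures drawn with matplotlib 3.10.9 in Python 3.11.15.

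The tests were tested on simulated data of 8713 genes, 200 of them with a raised SD. The variance test recovered 0% of genes with a 3-fold SD, 0% with a 5-fold SD and 68.2% with a 20-fold SD, with 0 calls outside the 200. The 20-fold size was added after a first simulation with 3-fold and 5-fold sizes gave no calls. The variance test can therefore find only very large differences between 4 arrays, and a gene that it did not call may still differ. A simulated list of 20 genes shifted by 0.5 on 1 array reached percentile 97.4. Of 200 random lists on the real arrays, 7.5% passed the 95th percentile, and of 200 unshifted lists in the simulated data 0% did (median percentile 35.1), where the genes with a raised SD were in the pool of the random lists and not in these lists.

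The lists, the tests and the rule for named genes were fixed before the data were examined. The named genes are the first 3 of each list, up to 10 variable genes with the largest SD with the 3 most variable list members among them, and list members whose detection goes against most of their list where these are 5 or fewer. Some genes that this rule names are not reported here. Other genes are named where a short list is given in full or where the text says that they were chosen after their values were seen. The 6 lists of the closing section were written after the files were opened and before their values were seen. Alternatives were other detection rules, normalizations, background correction, treatment of outlier flags, probe choice, filters, variance models, unmatched random lists, and leaving out each replicate. The normexp alternative was planned on the mean spot signal and was run instead on the median spot signal with the median background. Leaving out dim array areas and averaging replicates 3 and 4 were chosen after seeing the data. Dim areas were blocks of a grid of 12 by 10 per array with an excess of spots at least 1 log2 unit below the median of the other arrays.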

Results

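NR8383 is a macrophage cell line established from rat lung lavage, and the series exposed it for 4 h to 1.2 cm²/cm² of carbon nanotubes carrying amino groups, named NRCWE049 in the labels. The series describes a comparison of exposed with unexposed cells. The 4 arrays used here are all from exposed cells, and unexposed control arrays were not analysed here. The values below therefore describe exposed macrophages and cannot show which genes the nanotubes changed. Levels are log2 signals relative to the 75th percentile of the detected probes of the same array, given as mean ± SD over 4 biological replicates. A level serves to follow a gene between replicates and is not set against the level of another gene. Of 16581 named genes, 8713 (52.5%) were well above background on all 4 arrays and 6971 on none. The arrays detected 19143, 19311, 19215 and 19206 of 45598 probes in replicates 1 to 4. Their number limits the precision.

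The cells carried transcripts of macrophages and few of other lung cell types. Of 24 measured macrophage and myeloid genes, 20 were detected on every array. They included Csf1r, the receptor of the macrophage growth factor CSF1 (-1.28 ± 0.13, SD, n = 4), the lysosomal glycoprotein gene Cd68 (3.04 ± 0.09) and Spi1, which encodes the myeloid transcription factor PU.1 (0.89 ± 0.19). Of 14 alveolar macrophage genes, 12 were detected, among them Pparg, a transcription factor of alveolar macrophage differentiation (3.18 ± 0.15). Of both lists, 6 members were not well above background on all arrays. These were Adgre1, Cd163, Ccr2 and Cd86 of the first list, and the scavenger receptor gene Marco and the carbonic anhydrase gene Car4 of the second.

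Markers of other cell types were detected less often. Over the lists for T and NK cells, B cells, neutrophils, mast cells, epithelium, fibroblasts and endothelium, 15 of 68 measured genes (22.1%) were detected, against 32 of 38 (84.2%) in both macrophage lists (odds ratio 18.2, p = 5.85e-10, two-sided Fisher's exact test across genes). The surfactant gene Sftpc, the club cell gene Scgb1a1 and the epithelial adhesion gene Epcam were not well above background on any array, nor were Col1a1 and Pdgfra of fibroblasts, and Dcn was on 1 array. Epithelial markers (2 of 13, adjusted p = 0.0229, Fisher's exact test) and fibroblast markers (1 of 10, adjusted p = 0.0218, Fisher's exact test) were detected less often than other named genes. Fewer members were also detected among T and NK cell (4 of 14), B cell (2 of 7), neutrophil (2 of 8), mast cell (1 of 7) and endothelial markers (3 of 9), none past the test (adjusted p from 0.102 to 0.363, Fisher's exact test). The detected exceptions were Ager and Foxj1 of epithelium, Acta2 of fibroblasts, Pecam1, Cdh5 and Vwf of endothelium, Cd3d, Lck, Nkg7 and Gzma of T and NK cells, Pax5 and Ebf1 of B cells, S100a8 and Camp of neutrophils, and Hdc of mast cells. Vwf, which encodes von Willebrand factor, had a level of 1.87 ± 0.15, and Camp, the cathelicidin gene, 0.44 ± 0.15. The higher detection was past the test for the macrophage list (adjusted p = 0.0113, Fisher's exact test) and the alveolar macrophage list (adjusted p = 0.0312, Fisher's exact test). It was not past it for the macrophage list under Agilent's flag for positive and significant signal (odds ratio 3.11), and the alveolar macrophage list lost its call under 4 other detection rules.

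**Figure D1:**
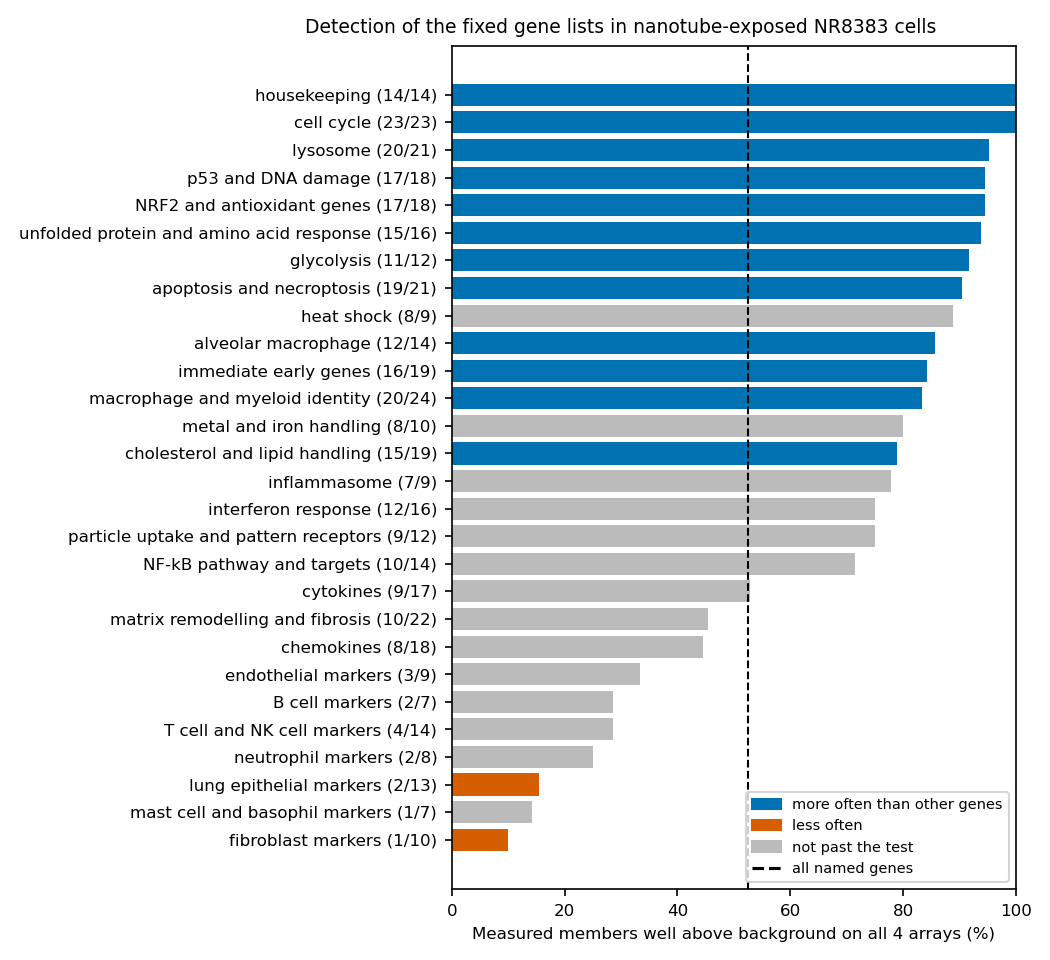
Percent of the measured members of each of 28 gene lists that were well above background on all 4 arrays of exposed NR8383 cells, with detected and measured members in brackets. The dashed line marks the 52.5% of all named genes; 12 lists lie above and 2 below it past an adjusted p of 0.05 in Fisher's exact test.

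Part of the inflammatory repertoire was detected in the exposed cells. Of 17 cytokine genes, 9 were detected: Il1b (1.42 ± 0.28, SD, n = 4), Tnf (1.46 ± 0.37), Il1a, Il18, Il1rn, Il33, Tgfb1, Osm and Csf3. Il6 was not well above background on any array. Il10, Il12a, Il12b, Csf1, Csf2, Lif and Ifnb1 were not detected by the rule of all 4 arrays. Of 18 chemokine genes, 8 were detected, among them the monocyte attractant Ccl2 (0.83 ± 0.33), the neutrophil attractant Cxcl2 (-0.12 ± 0.45) and Ccl3 (3.64 ± 0.21). Cxcl10 counted as not detected because its spot was flagged as an outlier on 1 array. Neither list differed from other named genes in detection (adjusted p = 1 for cytokines and 0.662 for chemokines, Fisher's exact test). The chemokine odds ratio was 0.722, and 1.40 without replicate 4; it was also above 1 under 4 other detection rules.

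**Figure D2:**
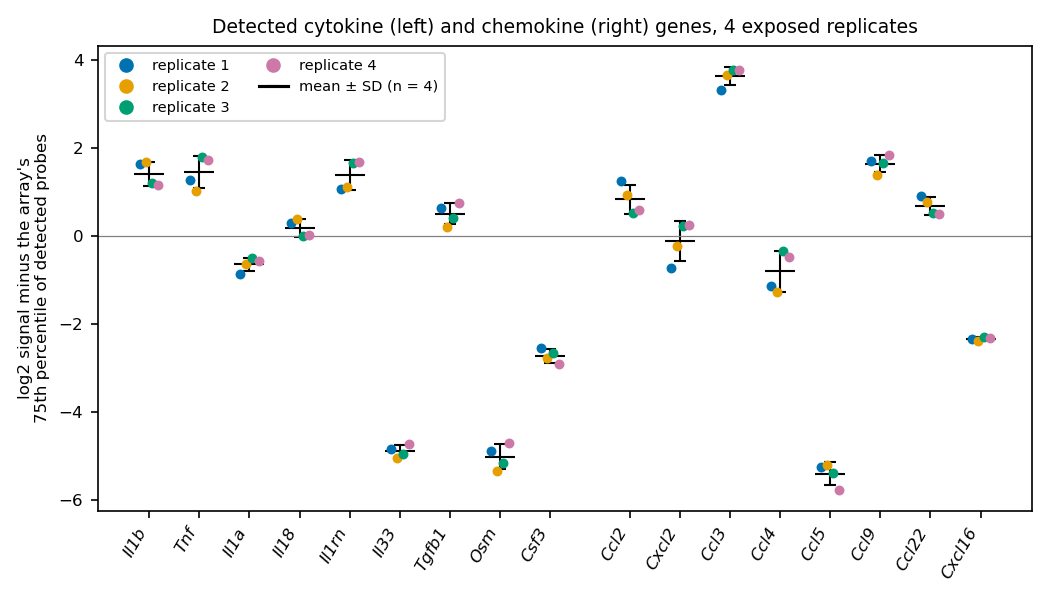
Levels of the 9 detected cytokine and 8 detected chemokine genes, as log2 signal minus the array's 75th percentile over detected probes; points are the 4 exposed replicates, bars the mean ± SD. Il1b lies at 1.42 and Ccl3 at 3.64, while Cxcl2 spreads with an SD of 0.45.

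Genes of the NF-kB, immediate early, inflammasome and interferon response lists were detected in part. Of 14 NF-kB pathway genes and targets, 10 were detected, including the inhibitor gene Nfkbia (0.52 ± 0.10, SD, n = 4), while the targets Ptgs2, Birc3, Traf1 and Nos2 were not (adjusted p = 0.228, Fisher's exact test). Of 19 immediate early genes, which respond to stimuli within minutes to hours, 16 were detected, more than among other genes (adjusted p = 0.0166, Fisher's exact test). Fos (-4.81 ± 0.15), Egr1 (-5.80 ± 0.79) and Atf3 (-0.25 ± 0.38) were among them, and Fosl1, Egr3 and Zfp36 were not detected. Housekeeping genes were also detected more often than other genes (14 of 14). For any list, such a call therefore does not show a response to a stimulus. Of 9 inflammasome genes, 7 were detected (adjusted p = 0.228, Fisher's exact test), including Nlrp3 (-2.49 ± 0.19), Casp1 (-2.74 ± 0.27) and Pycard (-0.55 ± 0.27); P2rx7 and Mefv were not. Of 16 interferon response genes, 12 were detected (adjusted p = 0.136, Fisher's exact test), with Isg15 at -2.78 ± 0.08, Irf7 at -2.72 ± 0.22 and Mx1 at -4.66 ± 0.30, and without Ifit1, Ifit3, Rsad2 and Ifih1.

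Antioxidant and lysosome genes were detected more often than other named genes, and the uptake receptor and metal lists did not pass that test. Of 18 NRF2 and antioxidant genes, 17 were detected (adjusted p = 0.00107, Fisher's exact test), among them the haem oxygenase gene Hmox1 (3.29 ± 0.54, SD, n = 4) and the quinone reductase gene Nqo1 (-2.77 ± 0.13), and the exception was Gclm, which encodes a glutamate-cysteine ligase subunit. Of 21 lysosome genes, 20 were detected (adjusted p = 0.000428, Fisher's exact test), with Lamp1 at 1.84 ± 0.08, the protease gene Ctsd at 6.02 ± 0.20 and Ctsb at 6.02 ± 0.06, and Ctsk was not. Of 12 particle uptake and pattern receptor genes, 9 were detected (adjusted p = 0.213, Fisher's exact test), including Cd36 (2.22 ± 0.13) and Tlr4 (-3.32 ± 0.12); the scavenger receptor genes Msr1, Scara5 and Colec12 were not. Of 10 metal and iron genes, 8 were detected (adjusted p = 0.168, Fisher's exact test), with the metallothionein gene Mt1 at 2.50 ± 0.06 and the ferritin gene Fth1 at 6.13 ± 0.26, and without Mt2A and Slc40a1.

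Genes of stress and death pathways were also detected, which does not show that these pathways were active. Of 18 p53 and DNA damage genes, 17 were detected (adjusted p = 0.00107, Fisher's exact test), with the cell cycle inhibitor gene Cdkn1a at 1.99 ± 0.35 (SD, n = 4), Mdm2 at -2.42 ± 0.18 and Gadd45a at -0.95 ± 0.23, and without Gadd45g. Of 21 apoptosis and necroptosis genes, 19 were detected (adjusted p = 0.00141, Fisher's exact test), including Bax (3.01 ± 0.17) and Mcl1 (-0.34 ± 0.06), and Bcl2 and Pmaip1 were not. Of 16 genes of the unfolded protein and amino acid response, 15 were detected (adjusted p = 0.00257, Fisher's exact test). They included the chaperone gene Hspa5 (2.21 ± 0.25), Ddit3 (0.96 ± 0.42) and Atf4 (3.79 ± 0.15), and Ern1 was the exception. Of 9 heat shock genes, 8 were detected (adjusted p = 0.0769, Fisher's exact test), with Hspb1 at -5.09 ± 0.24, and without the inducible Hspa1a.

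The cells expressed proliferation and metabolic genes. All 23 measured cell cycle genes were detected (adjusted p = 1.13e-05, Fisher's exact test), among them Mki67 (0.28 ± 0.41, SD, n = 4), Ccnb1 (0.47 ± 0.17) and Pcna (1.70 ± 0.07). All 14 housekeeping genes were detected (adjusted p = 0.00107, Fisher's exact test), with Actb at 5.86 ± 0.10, Gapdh at 6.23 ± 0.13 and Hprt1 at 1.19 ± 0.12. Of 12 glycolysis genes, 11 were detected (adjusted p = 0.0199, Fisher's exact test), including Hk2 (-2.90 ± 0.05), Slc2a1 (1.56 ± 0.10) and Ldha (5.52 ± 0.14), and Hk1 was not. Of 19 cholesterol and lipid genes, 15 were detected (adjusted p = 0.0441, Fisher's exact test), including the cholesterol exporter gene Abca1 (-4.67 ± 0.41). Fasn and Scd, each measured by 1 probe, were among those not detected, and the spot of Abcg1 was flagged as an outlier on 1 array. Of 22 matrix genes, 10 were detected (adjusted p = 0.570, Fisher's exact test), with Mmp12 at -4.42 ± 0.23 and Timp1 at -4.83 ± 0.15, and without Spp1. The glycolysis and cholesterol calls were lost under 2 other detection rules, and the cholesterol call also without replicate 1, 2 or 4.

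The 4 replicates were close to each other. The median SD of a detected gene was 0.151, the median ratio of its highest to its lowest replicate was 1.26, and 232 genes (2.66%) spanned more than 2-fold. Across genes, which are not independent replicates, Pearson correlations between arrays ran from 0.993 to 0.998. Levels differ widely between genes, so these correlations say little about how close the replicates were. One gene, Selenop, which encodes the selenium carrier selenoprotein P, varied by more than genes of like brightness (adjusted p = 0.0387, F test on limma residual variances). Its level was -5.28 in replicate 1 and -0.65, -1.02 and -0.84 in replicates 2 to 4, and its spot in replicate 1 lay in an area of the array where neighbouring spots were also low. The Selenop call was lost under quantile normalization, with the mean over probes, with no filter on dim probes, with no intensity trend and without replicate 2. It was also lost without replicate 1, which holds the deviating value. At an unadjusted p under 0.05 there were 375 genes, against 435.65 at the nominal rate. In the simulated data 1.97% of the unchanged genes passed this threshold, below the nominal rate. The count of 375 therefore cannot decide whether more genes varied than by chance. Selenop belongs to none of the 28 lists, so enrichment of the lists for variable genes could not be tested. Of the 295 detected members of the 28 lists, 2 (Sod1 and Tlr2) varied when the p-values were adjusted over these list members alone. Adjusted over the list alone, the chemokine list had 3 variable members (Ccl2, Ccl4 and Cxcl2), the NRF2 list 2 (Hmox1 and Sod1), and the NF-kB, uptake and cholesterol lists 1 each (Icam1, Tlr2 and Hmgcs1); Ccl4, Sod1, Icam1, Tlr2 and Hmgcs1 were named after their values were seen. The spots of Sod1, Tlr2 and Hmgcs1 lay in dim areas of single arrays, which includes both genes called over all list members. Of the 20 genes with the lowest variance p-values, 11 had a spot in a dim area, against 444 of 8713 tested genes. Replicate 1 was farthest for 14 of these 20 genes. Dim areas were themselves found from low spots, so genes low on 1 array fall in them more readily.

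**Figure D3:**
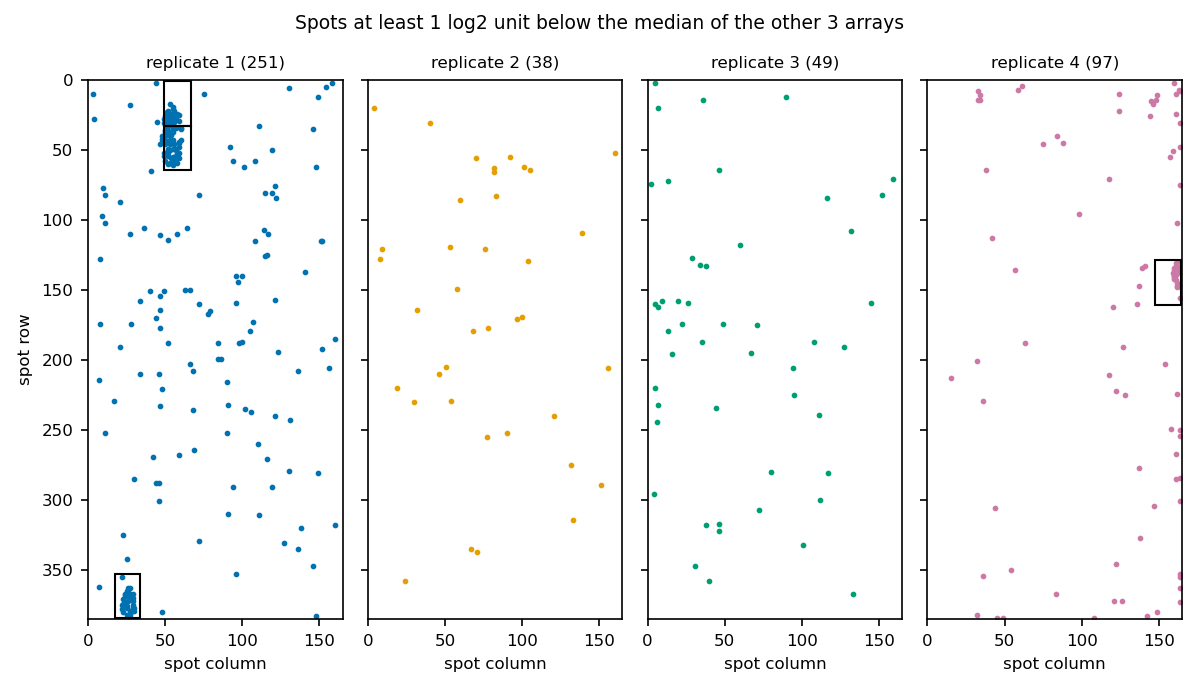
Position by row and column of spots at least 1 log2 unit below the median of the other 3 arrays, on each array, with their number in brackets. Boxes mark the 4 grid blocks with an excess of such spots, 3 in replicate 1 and 1 in replicate 4. In replicate 1, the blocks at rows 1 to 32 and 33 to 64 adjoin, and some low spots lie just outside them.

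Several lists moved together between replicates. The unfolded protein and amino acid response genes had the widest range of the 21 lists tested: their mean deviation was -0.25 in replicate 1, -0.04 in replicate 2, 0.10 in replicate 3 and 0.19 in replicate 4. This range of 0.438 lay at percentile 100 of 10000 random lists matched on signal, and replicate 1 was lowest for 12 of the 15 members. Cholesterol and lipid genes (range 0.321, percentile 99.9), uptake receptors (0.350, 99.8), immediate early genes (0.298, 99.7), cell cycle genes (0.184, 99.6), NF-kB genes (0.304, 99.1), matrix genes (0.314, 98.4) and NRF2 genes (0.179, 96.3) were also past the 95th percentile. That makes 8 lists, where about 1.58 would be expected from the share of random lists on these arrays that passed it. These 8 are not independent results. The unfolded protein, cholesterol, uptake receptor, immediate early, cell cycle and NF-kB lists were all lower in replicates 1 and 2 than in replicates 3 and 4. The matrix and NRF2 lists ran the other way, so all 8 lists split the replicates alike. Members of a pathway are regulated together and random genes are not, so the percentile describes these arrays and does not test the exposure. Without replicate 2, the percentiles were 81.7 for NF-kB genes, 48.4 for NRF2 genes, 80.4 for cell cycle genes and 84.3 for matrix genes. Other scalings also ended calls: NRF2 genes were at 80.6 with quantile normalization and 0.88 with median scaling, and matrix genes at 87.3 and 0.40. Median scaling brought cytokines (97.5) and glycolysis genes (96.2) past the 95th percentile, and ignoring outlier flags brought chemokines to 98.6. Median scaling used the median over all probes, of which 39.3% were detected on all arrays. It therefore rests on probes that were not detected. Uptake receptors were at 77.2 without replicate 1 and 94.5 without dim areas. Their member Tlr2, in a dim area, was at -1.54 in replicate 1 and 0.17, 0.35 and 0.33 in replicates 2 to 4. Part of the range of the uptake list therefore came from 1 spot. Immediate early genes were at 90.3 without replicate 4 and 83.2 with normexp. Their member Egr1, at a low mean level of -5.80, ran from -6.56 in replicate 1 to -4.91 in replicate 4. Part of the immediate early range therefore came from this gene. With no filter on dim probes, NF-kB genes were at 90.7, immediate early genes at 92.9 and matrix genes at 69.6.

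**Figure D4:**
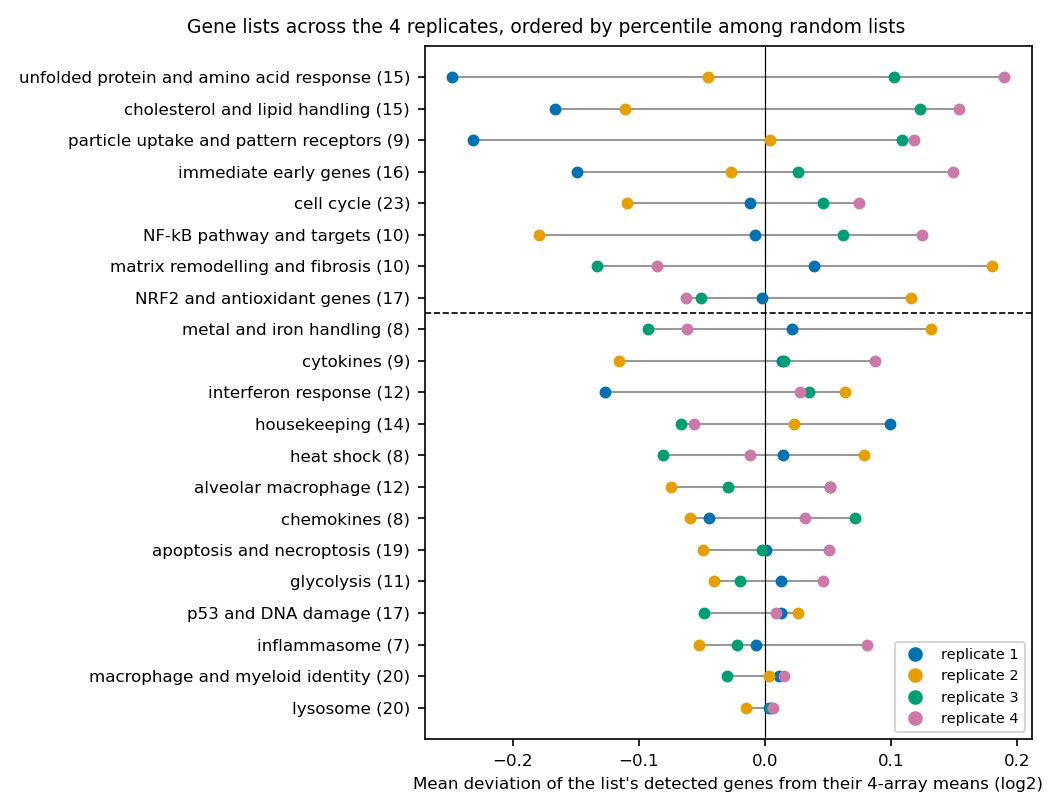
Mean deviation (log2) of the detected members of 21 gene lists from their means over the 4 exposed replicates, with the number of members in brackets; lists above the dashed line are past the 95th percentile of random lists. The unfolded protein and amino acid response runs from -0.25 in replicate 1 to 0.19 in replicate 4.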

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

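The test of neighbouring spots was chosen after the result was seen. Of 96 sets of 4 values, 7 had 1 replicate far from the other 3 by Dixon's ratio of gap to range, where about 4.8 would be expected by chance (1 in 20). Atf3, a stress-induced transcription factor gene, was apart in replicate 2 (ratio 0.9153), at 0.32 against -0.42, -0.42 and -0.48. Ccnb1 was lower in replicate 2 (ratio 0.8594), at 0.23 against 0.58, 0.53 and 0.56. Gadd45a was lower in replicate 1 (ratio 0.858), at -1.30 against -0.87, -0.82 and -0.80. Lck was higher in replicate 1 (ratio 0.8294), at -3.69 against -4.10, -4.07 and -4.15. The lysosome list was lower in replicate 2 (ratio 0.8645), within a range of 0.022. Nonuniform spots numbered 28 in replicate 1 and 1, 2 and 2 in replicates 2 to 4 (ratio 0.963).

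Selenop was low in replicate 1 (ratio 0.9205), with a log2 deviation of -4.43 from the median of the other arrays. The 52 detected spots of other genes within 5 rows and columns had a median deviation of -0.8762 on that array (95% interval of the median -1.15 to -0.62), so a local dim area is a candidate explanation. The lowest of these neighbours was at -3.15, but the lowest spot within 5 rows and columns of Atp5pb, a gene in the same dim area, was at -5.14, so the size of the Selenop deviation does not argue against the area. The upper quartile of the neighbours was -0.20, so part of them were little affected, and Selenop has 1 probe, which leaves no other spot to decide: the dim area and a true difference cannot be told apart. With 1 group in the design, no biological explanation was tested.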

How the results depend on the processing

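Leaving out dim areas and averaging replicates 3 and 4 were chosen after seeing the data. No paired analysis was possible because the samples form a single group. No result past its test reversed; the chemokine odds ratio, not past its test, crossed 1 without replicate 4 (0.722 to 1.40) and under 4 other detection rules, and the cytokine odds ratio stayed near 1. Under the flag for positive and significant signal, odds ratios past the threshold no longer were for macrophage (3.11), cholesterol (2.33) and glycolysis genes (6.84), and with signal above the negative control spots for cholesterol (2.47) and glycolysis genes (7.24). The alveolar macrophage list lost its call with detection on at least 3 arrays (5.15) or 1 array (4.36), the positive flag (8.08) and the negative control rule (3.95). Mast cell markers became less often detected past the threshold under the positive flag (0.103) and the negative control rule (0.110). The cholesterol odds ratio ran from 3.33 to 4.79 with each replicate left out, against 3.39 with all arrays. It was 4.79 without replicate 3, since Abcg1, flagged as an outlier on that array, then counted as detected. Without replicates 1, 2 and 4 it was 3.33, 3.33 and 3.35, no longer past the threshold (adjusted p = 0.071 in each case, Fisher's exact test). The causes of the other changes were not tested.

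The count of variable genes (1, limma) was 4 with outlier flags ignored, 11 with median scaling, 9 with the 75th percentile over all probes, 9 with replicates 3 and 4 averaged, and 0 with quantile normalization, the mean over probes, no filter on dim probes, no intensity trend or without dim areas; it ran from 0 to 9 with each replicate left out (0 without replicate 1 or 2, 9 without replicate 3 or 4). At an unadjusted p under 0.05 these settings gave 349 to 434 genes, and 915 without the filter. Without dim areas Selenop had no value in replicate 1 and was not tested. Lists past the 95th percentile numbered 5 without the filter on dim probes and 4 to 9 with each replicate left out, 4 without replicate 2. The median SD was 0.130 with normexp, 0.198 with median scaling and 0.116 to 0.160 with each replicate left out. NRF2 genes were at percentile 92.2 with the 75th percentile over all probes and with unmatched random lists, and matrix genes at 93.3 with normexp. Metal genes reached 98.4 without dim areas and 95.7 without replicate 1, and cytokines 95.5 without replicate 1. The unfolded protein and cholesterol lists stayed past the 95th percentile under every setting run. Median levels shifted by 7.72 with median scaling, 3.53 with the 75th percentile over all probes and 0.151 with normexp. Genes near background are limited by signal over background.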

Other observations

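The tests of members outside dim areas, of quantile normalization and of 1 labelled sample on both arrays were chosen after the results were seen. Gene groups outside the 28 lists were also read. Of 12 complement genes, 9 were detected, among them the properdin gene Cfp (2.68 ± 0.17, SD, n = 4), C2 (0.91 ± 0.07) and the C5a receptor gene C5ar1 (0.08 ± 0.07), while C1qa, C1qb and C1qc were not well above background on any array. Of 10 genes of MHC class II and its assembly, 4 were detected. The peptide loading genes RT1-DMa (2.58 ± 0.27) and RT1-DMb (2.27 ± 0.15) were, and the invariant chain gene Cd74 and the regulator Ciita were not. Of the class II chain genes, RT1-Bb (-6.23 ± 0.31) and RT1-Db1 (-4.19 ± 0.17) were detected, and RT1-Ba and RT1-Da were not.

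Of 15 eicosanoid genes, 6 were detected, including Alox5 (3.54 ± 0.06), Lta4h (3.86 ± 0.09) and Tbxas1 (3.49 ± 0.07) of leukotriene and thromboxane synthesis. Alox5ap and Ltc4s, also of leukotriene synthesis, were not detected by the rule of all 4 arrays. Ptgs1 was detected (0.47 ± 0.11) and Ptgs2 was not. Of 16 cytokine receptor genes, 12 were detected, with Tnfrsf1a at 1.53 ± 0.10 and without Tnfrsf1b and Il1r1. Of 12 Toll-like receptor genes, 5 were detected, and of 11 Siglec and C-type lectin genes, 4, with Clec7a, the beta-glucan receptor gene, at 2.30 ± 0.18. None of these 6 lists differed from other genes in detection (lowest adjusted p = 0.456, Fisher's exact test), and these genes were chosen after their values were seen.

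The unfolded protein and amino acid response genes spread together between replicates, lowest in replicate 1. The range of 0.438 was 0.4134 over the 14 members outside dim areas and 0.4739 under quantile normalization, where 95% of random lists stayed below 0.172 in both cases. With any 1 member left out these ranges were at least 0.377 and 0.438, which argues against local dim areas and brightness-dependent scaling as the whole cause. Slide position and differences in culture, labelling or RNA handling stay open, since each replicate had its own position. The signal at the 75th percentile was also lower in replicates 1 and 2 (1970 and 1980) than in replicates 3 and 4 (2493 and 2402.5). Whether the list shifts follow this difference in array signal was not tested beyond quantile normalization. No biological explanation was tested, as the design gives 1 group, and a difference in stress between cultures may be named only as a hypothesis.

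Replicates 3 and 4 were the most alike, with a median absolute difference of 0.0847 between them and 0.149 to 0.206 in other pairs. Among bright genes the pair's difference was 0.5921 of that of the next closest pair, which argues against lower noise in dim genes as the cause. Over 980 probes with 10 spots each, their difference was 1.653 times its standard error from the spots, where 0.688 is expected by chance and other pairs had 2.97 to 4.13. They differed by more than spot noise and were kept as 2 replicates. Spot noise leaves out error between hybridisations, so 1 RNA sample on both arrays and close cultures cannot be told apart.

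Outside dim areas, Gdf15, a stress-induced cytokine gene, spanned 3.71-fold and was lowest in replicate 1 (-0.73). Lcn2, the lipocalin 2 gene, spanned 2.71-fold and was highest in replicate 1 (4.50). Hmox1 spanned 2.16-fold and was higher in replicates 1 and 2 (3.67 and 3.82) than in replicates 3 and 4 (2.72 and 2.95). Gdf15, Lcn2 and Hmox1 did not pass the variance test (adjusted p = 0.233, 0.351 and 0.636, limma residual variances). Other genes outside dim areas spanned more, such as Dnajc17 (5.00-fold), Mitf (4.42-fold) and Cyp4a8 (4.04-fold), and did not pass it either. All of these genes but Hmox1 were chosen after their values were seen.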
